A study of Homo sapiens with 20 samples.

How the data were processed

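Gene expression was measured by RNA sequencing in epithelial cells of the human prostate that were sorted by flow cytometry and not cultured. The gates took epithelial cells and divided them by the surface protein CD49f, the integrin alpha 6 subunit encoded by ITGA6, which is high on basal and low on luminal cells. Per the labels, the 20 libraries came from 8 donors and from tissue called benign or cancer. They formed 4 groups of 5 libraries: benign basal, benign luminal, cancer basal and cancer luminal. Per the labels' protocols, total RNA was extracted with a column kit, amplified with the Ovation RNA-seq V2 kit and made into libraries with the PrepX DNA kit. These kits amplify from small amounts of RNA, and no source used here states that strand was kept, so reads of antisense or overlapping genes cannot be told apart.

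The authors deposited one table of log2 values, with 20502 gene rows and a column for each library. Per the submitters' processing notes, CASAVA 1.8.2, RSEM 1.2.25 and the hg19 genome build were used, and the annotation was not given in the sources used here. The scale was worked out from the deposited log2 values and is not stated by a source. After raising 2 to each value and subtracting 1, the upper quartile of the values above 0 lay between 997.3 and 1000.5 in each library. The deposited values therefore hold the logarithm to base 2 of an estimated read number scaled to a common upper quartile, plus 1. The lowest deposited value was 0. A fold change on this scale understates the change of genes near 0. RSEM divides reads that match several genes among them, so near-identical genes are uncertain. Among the genes named here this concerns ANXA8 and ANXA8L2, the histone genes, HBA1 and ribosomal protein genes with processed copies. TARP overlaps the T cell receptor gamma locus, and PCA3 lies antisense to another gene, so both are uncertain as well.

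Depth was recovered from the steps of low values. In each library between 93.1% and 94.9% of the linear values below 50 reads lay within 0.03 reads of a whole multiple of a single step. Dividing by that step gave between 11.7 and 62.0 M estimated reads per library. As RSEM also gives fractions of reads, the table was treated as log2 values and not as counts.

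The 2 rows that shared a symbol were left out, as were 86 genes that are never reported by library here (XIST, TSIX, Y-linked genes and genes with common whole-gene deletions). Of the 20414 genes kept, 19814 had a symbol or synonym in the reference table, which was used for names only. No coordinates are given, because the table holds none and the reference at hand is of another build. A gene was tested when its value was above 0 in at least 5 libraries, which left 17823 genes and removed 2591.

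Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. A linear model with 1 mean per group was fitted to all 20 libraries, so that the 4 groups shared an estimate of the spread. Moderated statistics used a mean-variance trend and robust estimation (statmod 1.5.0), and p-values were adjusted by the Benjamini-Hochberg method over the 17823 genes, at a threshold of 0.05. All limma tests used both tails. There were 6 contrasts: basal against luminal in benign tissue, in cancer tissue and as the mean of both, cancer against benign in basal and in luminal cells, and the interaction of population and tissue. Errors of fold changes are limma's moderated standard errors, and group values are given as mean and SD over 5 libraries.

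A set of 38 gene lists was fixed before the data were examined: markers of the sorted cells and of other cell types, pathways, and genes known to be high or low in prostate cancer. The list of mitochondrially encoded genes had 0 members in the table and was not tested. The other 37 were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera asks whether a list stands apart from the other genes. It was repeated with the correlation estimated from the data, which allows for members that vary together, and fry was used to ask whether a list moved on balance one way. With the estimated correlation the basal epithelial markers passed in the 3 basal against luminal contrasts, and no other list passed in any contrast.

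The genes named in the text were also chosen by a rule, fixed at the same time as the lists. In each contrast of groups it takes the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at least 7.39, the median level. Where no gene passed, it takes the 5 smallest p-values. It adds a set of fixed markers (ITGA6, KRT5, TP63, KRT8, KLK3, AMACR, PCA3 and others), and the 3 members of each list described with the smallest p. For the interaction it takes the 5 smallest p-values if none passes. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here.

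Several donors gave more than 1 library. Benign basal and luminal libraries shared 5 donors, cancer basal and luminal 3, benign and cancer basal 4, and benign and cancer luminal 2. The pairing by donor comes from the labels. It was checked by correlating the libraries' deviations from their group means: the 20 pairs of libraries from the same donor had a median correlation of 0.29 (0.11 to 0.53), against a median of -0.04 for 130 pairs from different donors and groups. Each library was also matched against the libraries of the other groups only. Of 18 libraries with a partner, 17 correlated best there with a library of their own donor. A fit with the donor as a block was therefore run beside the unblocked one, as a random effect (residual correlation 0.41) and as a fixed effect. No columns were identical, and the highest correlation between 2 libraries was 0.9853. This excludes exact copies of a column but not repeated sequencing of a sample.

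Other settings fixed at that time were no filter, a filter at the median level, an offset of 16 before taking logarithms, quantile normalization, median centring, fits to the groups compared alone, the donor block, plain empirical Bayes variances, library weights, and leaving out each library in turn. A further 2 were added after the data were seen: voom weights on the estimated reads, and a fit without the 2 basal libraries nearest to the luminal ones on the first principal component. Simulated data used the real means and spreads, with a common mean for the 2 groups compared except in genes set to change. Noise was drawn independently for each gene and library, without the correlation within donors. The changed genes came from those at or above the median level, so recovery of lower genes was not tested. For cancer against benign basal cells, the limma step on 17823 genes recovered 66% of 100 genes changed by 1 log2 unit. It recovered 97% of 100 genes changed by 2 log2 units. For cancer against benign luminal cells it recovered 75% and 97%, for basal against luminal cells in benign tissue 84% and 97%, and in cancer tissue 75% and 95%.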

Results

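Basal and luminal epithelial cells were sorted from benign and from cancer tissue of the human prostate, and the RNA of 5 libraries per group was sequenced. The series title places the work in the study of a basal stem cell signature in aggressive prostate cancer. Estimated depth was 23.4 ± 9.3 M reads (M, read number divided by 10 to the power of 6) in benign basal, 28.5 ± 8.1 in benign luminal, 21.7 ± 6.8 in cancer basal and 25.5 ± 20.6 in cancer luminal libraries (SD, n = 5 each). A single cancer luminal library reached 62.0 M reads. The number of genes above 0 was similar, at 16661.6 ± 487.2, 17112.8 ± 367.0, 16339.4 ± 587.0 and 16622.6 ± 683.1 in the same order. The sort was visible in ITGA6, which encodes CD49f: its log2 level was 2.58 ± 0.29 (SE) higher in basal than in luminal cells of benign tissue (limma, adjusted p = 3.21e-06) and 2.53 ± 0.29 higher in cancer tissue (adjusted p = 2.63e-06).

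The sorted population was the main division among the libraries. The first principal component of the 1000 most variable genes held 59.5% of their variance, and population accounted for 94.5% of its scores, against 0.1% for tissue. Components 2, 3 and 4 held 6.8%, 6.0% and 4.8%. Donor accounted for between 86.3% and 89.3% of the scores on these.

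**Figure D1:**
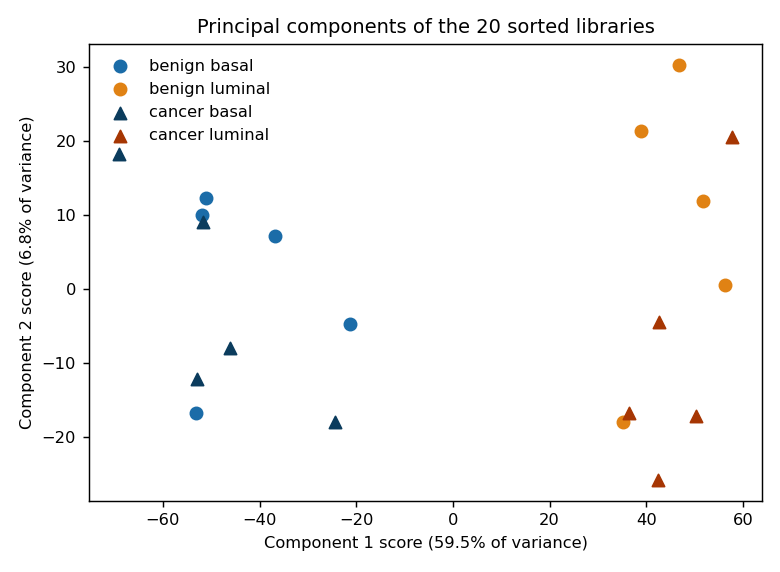
Scores of the 20 libraries on components 1 and 2 of the 1000 most variable genes, with a point per library, color for the group and triangles for cancer tissue. Basal libraries lie between -69.0 and -21.3 on component 1 and luminal libraries between 35.1 and 57.7, while cancer and benign libraries are mixed.

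Basal and luminal cells were compared first in the tissue that the labels call benign. Genes that mark the basal layer were far higher in basal cells. COL17A1, a hemidesmosome collagen, was 5.25 ± 0.37 log2 units higher (adjusted p = 2.76e-08), and TP63, the transcription factor that maintains basal epithelia, 4.23 ± 0.35 higher (adjusted p = 1.2e-07). Genes of the luminal prostate cell were far lower: KLK3, which encodes prostate-specific antigen, fell by 5.59 ± 0.95 (adjusted p = 0.000259), and FOLH1, which encodes prostate-specific membrane antigen, fell by 6.31 ± 1.16 (adjusted p = 0.000517). The 5 basal and the 5 luminal libraries did not overlap for COL17A1, TP63, KLK3 and FOLH1.

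The other largest rises were in the cadherin CDH13 (4.95), the epidermal transcription factor BNC1 (4.61), ZBED2 (4.39), the calcium sensor VSNL1 (4.19), ANXA8L2 (4.14), the Notch receptor NOTCH4 (4.07), ANXA8 (3.88) and the membrane glycoprotein PDPN (3.86). The other largest falls were in the neuropeptide NPY (-5.95), the kallikreins KLK2 (-5.60) and KLK4 (-5.41), CWH43 (-5.59), CPNE4 (-5.44), the phospholipase PLA2G2A (-5.41), MYBPC1 (-5.37) and the fatty acid elongase ELOVL2 (-5.26). All 16 log2 fold changes were past the threshold, and their largest adjusted p was that of NPY, at 0.00432. The keratin of basal cells KRT5 rose by 3.61 ± 0.51 and the luminal keratin KRT8 fell by 1.2 ± 0.17. The prostate cancer transcript PCA3 fell by 4.55 ± 0.77 (adjusted p = 0.000179), while AMACR differed by -1.08 ± 0.48 without passing (adjusted p = 0.103).

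Of the 22 basal epithelial markers 14 rose and 0 fell (16 rose adjusted over the list alone), with a median log2 change of 1.89 (camera, adjusted p = 9.36e-12, and adjusted p = 0.0087 with an estimated correlation). ITGB4, the integrin partner of ITGA6, rose by 2.69 ± 0.36. Of the 22 luminal secretory markers 18 fell and 0 rose (21 fell adjusted over the list alone), with a median of -2.92 (adjusted p = 4.93e-14, but adjusted p = 0.109 with an estimated correlation). Examples were TMPRSS2 (-2.69), SLC45A3 (-4.25) and CREB3L4 (-2.27). Of 26 androgen response genes 13 fell and 2 rose (14 and 3 adjusted over the list alone), among them TPD52 (-1.93), MAF (-3.24) and STEAP4 (-4.03). That list passed at an adjusted p of 0.000112 (adjusted p = 0.281 with an estimated correlation). Of 21 genes known to be high in prostate cancer 11 fell in basal cells (17 adjusted over the list alone; adjusted p = 3.8e-06, and adjusted p = 0.32 with an estimated correlation), such as GOLM1 (-2.51) and TMEFF2 (-5.24).

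Part of the adhesion and matrix genes rose in basal cells. Of 22 focal adhesion and actin genes 11 rose (11 rose and 1 fell adjusted over the list alone; adjusted p = 1.34e-05, and adjusted p = 0.32 with an estimated correlation), led by the caveolins CAV1 (3.03) and CAV2 (2.26) and the actin crosslinker FLNA (1.88). Of 20 basement membrane and matrix genes 6 rose and 1 fell (the same numbers adjusted over the list alone; adjusted p = 0.000449, and adjusted p = 0.383 with an estimated correlation). The paired collagen genes COL4A6 (3.62) and COL4A5 (3.09) and the anchoring fibril collagen COL7A1 (3.31) led this list.

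Of 28 Wnt pathway genes 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.000254, and adjusted p = 0.327 with an estimated correlation). The receptor FZD6 rose by 1.30. The members that fell were the receptor FZD8 (-2.13) and AXIN2 (-1.87), which is both a target and an inhibitor of the canonical pathway. Of 22 axon guidance and neurotrophin genes 8 rose (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.000449, and adjusted p = 0.32 with an estimated correlation), among them EFNB1 (2.12), PLXNA2 (1.96) and NRG1 (2.43). Of 22 ribosome biogenesis genes 15 rose and 0 fell (16 rose adjusted over the list alone), with a small median of 0.58 (adjusted p = 1.03e-08, and adjusted p = 0.32 with an estimated correlation). Examples were the nucleolar proteins NCL (0.85) and NPM1 (0.94) and the pseudouridine synthase DKC1 (0.92).

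Lists of basic cell functions passed as well. Of 82 ribosomal protein genes 7 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.18, adjusted p = 0.000769, and adjusted p = 0.846 with an estimated correlation). RPS27L, a p53-induced paralog of a ribosomal protein, fell by 1.98, while RPL4 rose by 0.49. Of 81 oxidative phosphorylation genes 11 rose and 4 fell (9 and 3 adjusted over the list alone; median 0.11, adjusted p = 0.0453, and adjusted p = 0.846 with an estimated correlation). ATP5B rose by 0.77 and NDUFV2 fell by 1.21. Of 20 endoplasmic reticulum genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.007, and adjusted p = 0.722 with an estimated correlation): CANX rose by 0.51, and XBP1, a regulator of secretory capacity, fell by 1.09. Of 64 replication dependent histone genes 18 fell (19 adjusted over the list alone; median -0.77, adjusted p = 0.000449, and adjusted p = 0.633 with an estimated correlation), with HIST1H2AC at -2.44. Of 20 cholesterol and fatty acid synthesis genes 5 fell (6 adjusted over the list alone; adjusted p = 0.0246, and adjusted p = 0.68 with an estimated correlation), with ELOVL7 at -1.28 and HMGCS1 at -1.14.

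Some lists that mark other cells passed at the preset correlation. Of 16 club and hillock cell markers 7 fell in basal cells (9 adjusted over the list alone; adjusted p = 0.00726, and adjusted p = 0.633 with an estimated correlation), such as TFF3 (-4.21) and CP (-4.31). Of 9 MHC class II genes 5 fell (7 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.633 with an estimated correlation), including HLA-DMA (-1.58) and CIITA (-1.46). Of 12 endothelial markers 7 rose (7 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.633 with an estimated correlation), among them VWF (1.89), TEK (2.40) and EMCN (2.21). Some of these calls ended without a single library: VWF without benign basal replicate 2 or benign luminal replicate 1, 3 or 5, TEK without benign basal replicate 2 or 5 or benign luminal replicate 3 or 4, and CIITA without benign basal replicate 5 or benign luminal replicate 2. The 12 endothelial markers had a mean log2 level of 5.09 ± 0.43 in benign basal and 3.87 ± 0.58 in benign luminal libraries (SD, n = 5). The basal epithelial markers stood at 12.37 ± 0.16 and 10.41 ± 0.29. Lists of T and NK, myeloid, B and plasma, mast, red blood, Schwann, smooth muscle, fibroblast, urothelial and seminal vesicle cells did not pass, nor did the mesenchymal, Notch, stem and progenitor, proliferation, immediate early, heat shock, NF-kB, interferon, neuroendocrine and cancer-low lists.

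In all, limma called 4699 of 17823 genes, of which 1930 were higher and 2769 lower in basal cells, and 2463 differed by at least 2-fold. In 18.95% of genes the groups did not overlap, against 0.79% by chance. With the donor as a block the count was 7087 as a random and 7364 as a fixed effect, and no gene named here lost its call as a random effect. The share of calls that were higher in basal cells was 41.1%, but 53.8% after quantile normalization and 58.6% after median centring, which moved the median log2 change of all genes from -0.07 to 0.07 and 0.09. None of the named genes past the threshold turned direction under either scaling. Of the 17 lists, 14 passed whichever library was left out. The oxidative phosphorylation list did not pass without benign basal replicate 4 or 5, benign luminal replicate 1 or 2 or cancer luminal replicate 2. The cholesterol list did not without benign basal replicate 1 or benign luminal replicate 3, nor the endoplasmic reticulum list without benign basal replicate 5.

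**Figure D2:**
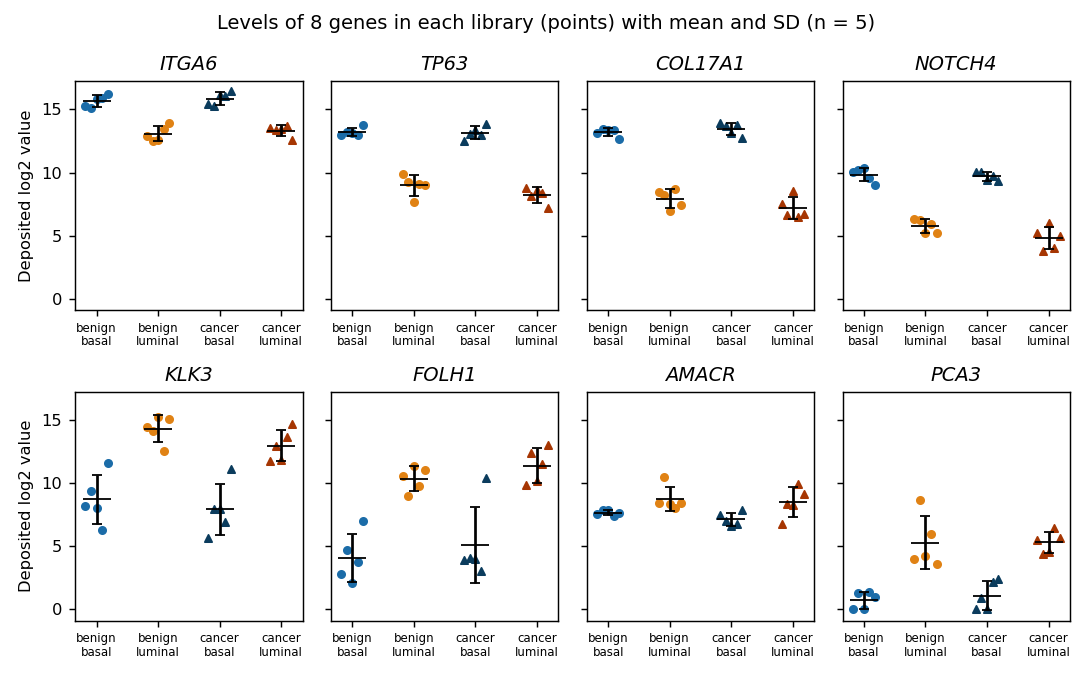
Deposited log2 values of 8 genes in each of the 20 libraries, with the mean and SD of each group of 5. ITGA6, TP63, COL17A1 and NOTCH4 have higher means in both basal groups, and KLK3, FOLH1 and PCA3 in both luminal groups. FOLH1 stands at 10.43 in cancer basal replicate 5, above cancer luminal replicates 1 (9.82) and 3 (10.16).

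The same comparison in cancer tissue asked whether basal and luminal cells are as distinct there. COL17A1 rose by 6.26 ± 0.37 (limma, adjusted p = 2.54e-09) and TP63 by 4.92 ± 0.35 (adjusted p = 1.02e-08) in basal cells of cancer tissue. The labels name the tissue and do not say whether the sorted cells were malignant. KRT5 and KRT14, the keratin pair of basal cells, rose by 4.62 ± 0.51 and 4.22 ± 0.44, and NGFR, the low-affinity neurotrophin receptor, by 4.96 ± 0.66. KLK3 fell by 5.06 ± 0.95 (adjusted p = 0.000551). KRT8 fell by 1.04 ± 0.17.

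The other largest rises were VSNL1 (5.50), CDH13 (5.14), ANXA8L2 (5.08), NOTCH4 (4.90) and ZBED2 (4.72). The largest falls were TARP (-6.39), TRIM58 (-6.33), the trypsin inhibitor SPINK1 (-6.23), the tryptophan-degrading enzyme IDO1 (-5.91), the olfactory receptor OR51E2 (-5.83), the mucin MUC5B (-5.70), CWH43 (-5.44), DTNA (-5.43), KLK4 (-5.29) and the serine protease inhibitor SERPINA3 (-5.27). The largest adjusted p among these 15 was that of ZBED2, at 0.00139. PCA3 fell by 4.23 ± 0.77 and AMACR fell by 1.33 ± 0.48 (adjusted p = 0.0398). The call of AMACR was borderline: its groups overlapped, and 13 of 32 alternatives ended it. Among these was leaving out any of cancer basal replicates 1 to 4 or cancer luminal replicates 2 to 5, and without cancer luminal replicate 4 the difference was -0.97 (adjusted p = 0.125, range over its alternatives 0.00322 to 0.2).

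Of the 22 basal epithelial markers 20 rose and 0 fell (20 adjusted over the list alone; median 2.38, adjusted p = 2.17e-15, and adjusted p = 0.00194 with an estimated correlation). Of 22 luminal secretory markers 18 fell (19 adjusted over the list alone; median -2.94, adjusted p = 2.55e-11, and adjusted p = 0.23 with an estimated correlation), with TMPRSS2 at -2.95, SPDEF at -2.92 and STEAP2 at -1.57. Of 26 androgen response genes 15 fell and 1 rose (the same numbers adjusted over the list alone; adjusted p = 0.000176, and adjusted p = 0.231 with an estimated correlation), with TPD52 at -2.0, STEAP4 at -4.53 and ACSL3 at -1.05. Of 21 genes known to be high in prostate cancer 18 fell (18 adjusted over the list alone; median -3.23, adjusted p = 4.93e-09, and adjusted p = 0.231 with an estimated correlation), such as GOLM1 (-3.27), GCNT1 (-1.86) and TMEFF2 (-5.33).

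Of 22 focal adhesion and actin genes 14 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 2.88e-06, and adjusted p = 0.293 with an estimated correlation), with CAV1 at 3.70, FLNA at 2.25 and the integrin ITGA3 at 1.66. Of 20 basement membrane and matrix genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000554, and adjusted p = 0.43 with an estimated correlation), with COL4A6 at 4.21, COL4A5 at 3.14 and COL7A1 at 3.50. Of 28 Wnt pathway genes 15 rose and 3 fell (15 and 3 adjusted over the list alone; adjusted p = 0.00127, and adjusted p = 0.441 with an estimated correlation). The ligand WNT10A rose by 4.10 and FZD6 by 1.15, and AXIN2 fell by 2.34. Of 22 axon guidance and neurotrophin genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.401 with an estimated correlation), with EFNB1 at 2.61, PLXNA2 at 2.03 and NRG1 at 3.14.

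Of 22 ribosome biogenesis genes 18 rose and 0 fell (20 rose adjusted over the list alone; adjusted p = 1.42e-10, and adjusted p = 0.231 with an estimated correlation), with NCL at 0.83, DKC1 at 1.01 and NPM1 at 1.02. Of 82 ribosomal protein genes 16 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 2.1e-05, and adjusted p = 0.817 with an estimated correlation), with RPL4 at 0.46 and RPS27L at -2.38. Of 81 oxidative phosphorylation genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.833 with an estimated correlation), with NDUFV1 at 0.76 and NDUFV2 at -1.38. Of 20 cholesterol and fatty acid synthesis genes 10 fell (12 fell and 1 rose adjusted over the list alone; adjusted p = 0.00566, and adjusted p = 0.63 with an estimated correlation), with HMGCS1 at -1.10 and ELOVL7 at -1.04.

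Of 9 MHC class II genes 8 fell (9 adjusted over the list alone; median -2.69, adjusted p = 0.000887, and adjusted p = 0.48 with an estimated correlation), with HLA-DRA at -3.09 and HLA-DMA at -2.27. Of 16 club and hillock cell markers 7 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.0206, and adjusted p = 0.781 with an estimated correlation), with CP at -5.22. Of 12 endothelial markers 4 rose (5 adjusted over the list alone; adjusted p = 0.0325, and adjusted p = 0.781 with an estimated correlation), with TIE1 at 2.54 and CDH5 at 2.60. The call of CDH5 ended in 1 of its 31 alternatives (limma, highest adjusted p = 0.0631). Lists that passed here and not in benign tissue were these: 3 of 15 interferon response genes fell, such as IRF7 (-1.48), 6 of 15 neuroendocrine markers, such as CALCA (-4.35), and 2 of 14 fibroblast markers, APOD (-3.55) and COL1A1 (-1.49). Adjusted over the list alone 3, 7 and 2 fell. Their adjusted p-values were 0.0346, 0.0356 and 0.0284, and the adjusted p-values with an estimated correlation were 0.833, 0.506 and 0.833. The mean log2 level of the fibroblast markers varied widely among cancer luminal libraries, at 6.55 ± 2.23 (SD, n = 5, from 3.5 to 9.11). In cancer basal libraries it was 4.85 ± 0.72. Smooth muscle markers were also spread in cancer luminal libraries (6.17 ± 1.33), and the source of these transcripts was not tested. For the interaction of population and tissue, camera passed the fibroblast list but not the interferon or neuroendocrine list. In the comparison within cancer tissue, the interferon list did not pass with the donor as a random block (adjusted p = 0.0749, range over its alternatives 0.000499 to 0.833). The histone list (0.0435, range 0.000334 to 0.977) and the endoplasmic reticulum list (0.016, range 0.000521 to 0.977) did. A fixed block ended the calls of the interferon and the cholesterol lists and also gave those of the histone and the endoplasmic reticulum lists. Of the 18 lists, 12 passed whichever library was left out. Single libraries ended the calls of the interferon and neuroendocrine lists (5 libraries each), endothelial (4), fibroblast (3), club and hillock (2) and oxidative phosphorylation lists (1, cancer luminal replicate 1).

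Limma called 5251 genes in cancer tissue, 2257 higher and 2994 lower in basal cells, of which 2850 differed by at least 2-fold. In 16.79% of genes the groups did not overlap, against 0.79% by chance. The share of calls higher in basal cells was 43.0%, 53.6% after quantile normalization and 55.9% after median centring.

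**Figure D3:**
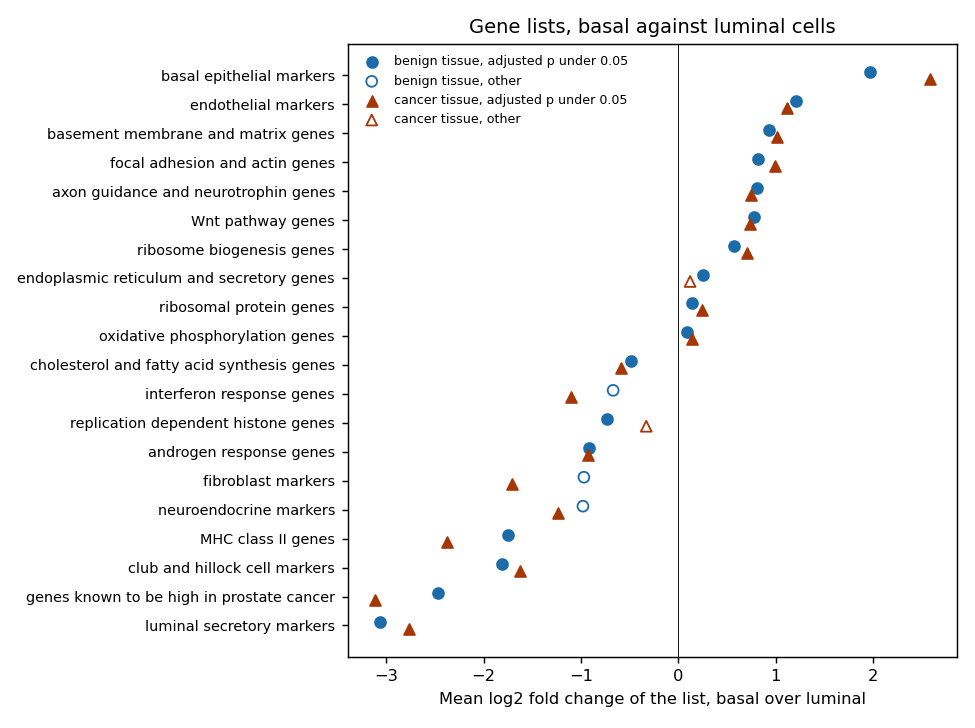
Mean log2 fold change, basal over luminal, of each list that passed in at least 1 tissue, with circles for benign and triangles for cancer tissue and filled symbols for an adjusted p under 0.05. The means run from -3.11 for genes known to be high in prostate cancer, in cancer tissue, to 2.58 for basal epithelial markers in cancer tissue.

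The population difference was then set side by side in both tissues. Of all genes, 3621 were called in both tissues in the same direction and 0 in opposite directions. There were 1490 genes higher in basal cells in both tissues and 2131 lower, where independent lists of these sizes would share 244 and 465. Across genes, which are not independent replicates, the log2 changes of the 2 tissues had a Pearson r of 0.865 (Spearman 0.796). Averaged over both tissues, limma called 7747 genes, 3356 higher and 4391 lower (43.3% higher, and 55.0% or 57.3% after quantile normalization or median centring). Of the lists, 18 passed for this mean. With tests limited to genes at or above the median level the count was 4901. Some donors gave libraries to both tissues, so the 2 sets of changes were not fully independent.

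**Figure D4:**
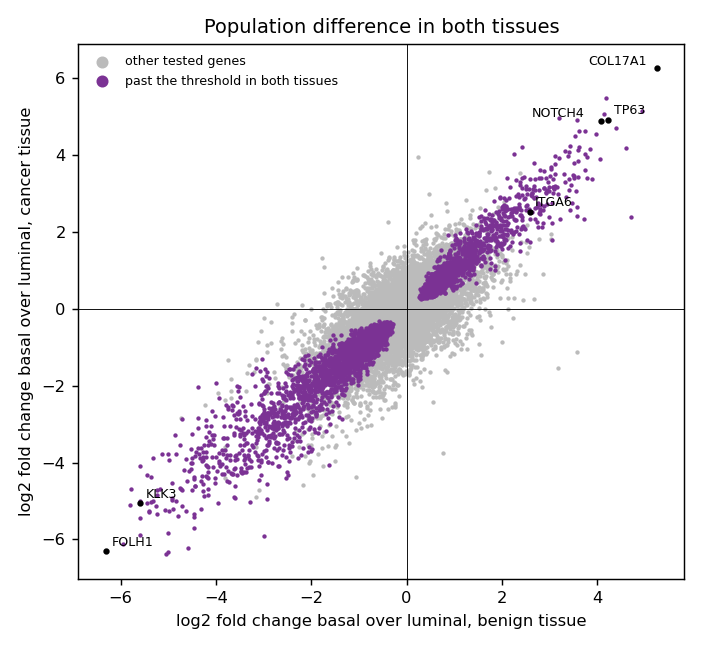
Log2 fold change, basal over luminal, of each tested gene in benign tissue (horizontal) and cancer tissue (vertical), with 3621 genes past the threshold in both tissues in purple. These genes lie at the lower left and the upper right.

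Cancer and benign tissue were compared within each population to ask what differs in cells of a tumor-bearing region. In basal cells no gene passed. The markers of the population were not called: TP63 differed by -0.05 ± 0.35, KRT5 by 0.51 ± 0.51 and ITGA6 by 0.19 ± 0.29, each at an adjusted p of 1 (limma, n = 5 against 5). The 5 smallest p-values, none past the threshold, belonged to ERP27 (-2.20), the transcription factor MYB (-0.95), the sodium channel gene SCN1A (-1.66), ZNF43 (-0.67) and the condensin subunit SMC2 (-0.43). With the donor as a block, ERP27, which encodes a protein of the endoplasmic reticulum, was the only gene called, at -2.39 ± 0.36 (adjusted p = 0.02, range over its alternatives 0.02 to 1).

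Camera passed 8 lists in basal cells, although 0 of their members were called, also adjusted over the list alone. Relative to the other genes, whose median change was -0.09, the lists of ribosomal protein genes (median 0.12), ribosome biogenesis (0.19), oxidative phosphorylation (0.05), basal epithelial markers (0.14), endoplasmic reticulum (0.09), MHC class II (0.42) and focal adhesion genes (0.08) lay higher, and immediate early genes (-0.35) lower. Their adjusted p-values ran from 4.16e-11 to 0.0337, while the adjusted p-values with an estimated correlation were at least 0.663. Among the members with the smallest p-values were RPL8 (0.53), KRT14 (0.85), RRP9 (0.69), EGR1 (-0.78) and EGR2 (-1.21), each at an adjusted p of 1. Either form of the donor block ended 2 calls, those of the focal adhesion list (random block, adjusted p = 0.223, range over its alternatives 0.00607 to 0.978) and the MHC class II list (adjusted p = 0.2, range 0.000507 to 0.978). The fixed block also gave 2 calls, those of the stem and progenitor and the NF-kB and cytokine lists. Of the 8 lists, 4 passed whichever library was left out, and single libraries ended the calls of the focal adhesion and immediate early lists (5 libraries each), endoplasmic reticulum (3) and MHC class II lists (2). Limma gave 720 genes with an unadjusted p under 0.05, where 891 are expected by chance, and the voom fit called 0 genes with 614 such p-values. The limma number depended on the setting. It was 1663 with the donor as a random block, 1723 with a fixed block and 1292 with library weights. Of fits that left out a library it was 426 without cancer basal replicate 3, 479 without benign basal replicate 3 and 1091 without cancer basal replicate 5.

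In luminal cells no gene passed either. For the known prostate cancer transcripts no difference passed: AMACR differed by -0.27 ± 0.48 (95% interval -1.26 to 0.73, adjusted p = 0.886) and PCA3 by 0.03 ± 0.77 (-1.57 to 1.64, adjusted p = 0.993). Both values depended on single libraries. Benign luminal replicate 2 was the highest of its group for AMACR (10.49, the others 8.05 to 8.47) and PCA3 (8.64, the others 3.56 to 6.0). It also lay above each cancer luminal library for AMACR (6.73 to 9.94) and PCA3 (4.42 to 6.45). What set this library apart was not tested. Without benign luminal replicate 2 the differences were 0.17 for AMACR and 0.87 for PCA3. Without cancer luminal replicate 1 AMACR differed by 0.17 as well, and without single luminal libraries PCA3 ranged from -0.4 to 0.87. None of these passed. KLK3 differed by -1.31 ± 0.95 (adjusted p = 0.697) and KRT8 by -0.03 ± 0.17. The 5 smallest p-values were those of ADCK4 (-1.43), TMEM106C (1.23), NCRNA00092 (-2.09), CSRP2 (-0.71) and FAM153A (-1.96), each at an adjusted p of 0.554.

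Camera passed 16 lists in luminal cells, again with 0 members called and with an adjusted p of at least 0.511 with an estimated correlation. Immediate early genes lay lowest against the other genes, with a median of -0.84 (adjusted p = 6.39e-10). Of its 20 members 10 were lower adjusted over the list alone, with EGR1 at -1.27 ± 0.32, BTG2 at -1.10 ± 0.28 and IER2 at -0.88 ± 0.24. MHC class II genes had a median of 1.02 (adjusted p = 3.29e-06), with HLA-DRA at 1.64 ± 0.69. Genes known to be high in prostate cancer had a median of 0.76 (adjusted p = 1.72e-05), with GCNT1 at 0.91 ± 0.25 and GOLM1 at 0.76 ± 0.22, the 2 members higher adjusted over the list alone. Genes known to be low in prostate cancer had a median of -0.72 (adjusted p = 0.0151), with 4 members lower adjusted over the list alone and SLC18A2 at -2.49 ± 0.59, MME at -1.52 ± 0.44 and SLC14A1 at -0.97 ± 0.32.

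The remaining lists lay above or below the median change of all genes, -0.11. Lists above it were endoplasmic reticulum (median 0.24), fibroblast markers (0.57), ribosomal protein (0.04), proliferation (0.15), ribosome biogenesis (0.06), cholesterol synthesis (0.04) and neuroendocrine genes (0.29). Histones (-0.69), basal epithelial markers (-0.41), red blood cell markers (-0.64, with 2 members lower adjusted over the list alone), luminal secretory markers (-0.49) and stem and progenitor genes (-0.35) lay below. Fibroblast markers had a mean log2 level of 6.55 ± 2.23 in cancer and 5.92 ± 1.02 in benign luminal libraries (SD, n = 5). With the donor as a random block the cholesterol list did not pass (adjusted p = 0.535, range over its alternatives 0.000693 to 0.94). A fixed block for the donor gave 13 lists, of which 8 were among the 16. The 8 that did not pass were the lists of MHC class II, endoplasmic reticulum, ribosomal protein, cholesterol synthesis, stem and progenitor, neuroendocrine and red blood cell genes and of genes known to be high in prostate cancer. The 5 it gained were the androgen response, mesenchymal, Wnt, interferon and endothelial lists. Of the 16 lists, 5 passed whichever library was left out: immediate early, histone, endoplasmic reticulum, MHC class II and cancer-high genes. Limma gave 1503 genes with an unadjusted p under 0.05, against 891 by chance, and the voom fit called 0 genes with 1561 such p-values. The limma number was 1645 with the donor as a random block, 1460 with a fixed block and 2087 with library weights. It was 2404 without cancer luminal replicate 1 and 987 without benign luminal replicate 1. A typical 95% interval of a fold change reached 0.62 log2 units to either side in both tissue comparisons.

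**Figure D5:**
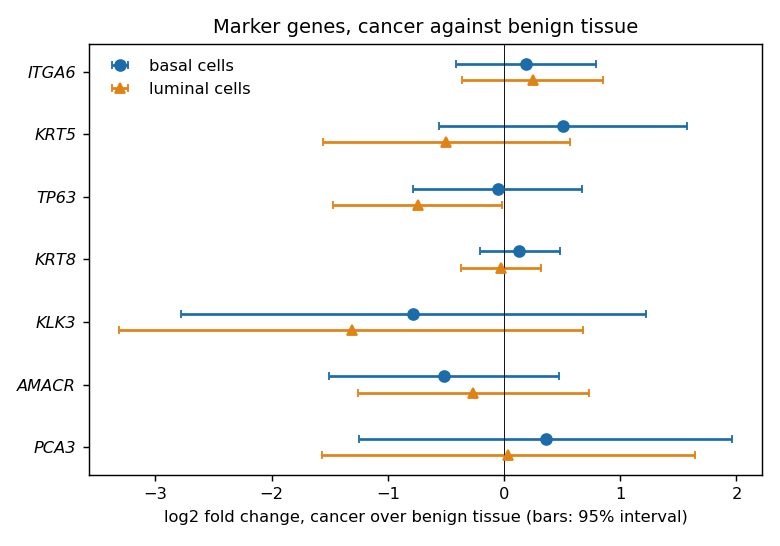
Log2 fold change, cancer over benign tissue, of 7 marker genes in basal (circles) and luminal cells (triangles), with 95% intervals that are not adjusted for the number of genes. None of these differences passed the adjusted threshold.

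The interaction, the difference between tissues in the basal to luminal change, was called for 0 genes by limma (407 unadjusted p-values under 0.05, with 891 expected by chance) and for 0 by the voom fit (392). The number of such p-values was 1040 with the donor as a random block, 1584 with a fixed block and 638 with library weights, and 0 genes were called in each. It was 650 without benign luminal replicate 4 and 805 without cancer luminal replicate 1. The smallest p-values included those of GAST (2.82) and SPP1 (-4.68), at an adjusted p of 0.999. Of the lists 9 passed camera, led by basal epithelial markers (median 0.56, adjusted p = 8.02e-06), of which 0 were called adjusted over the list alone and whose adjusted p was 0.141 with an estimated correlation. A fixed block for the donor gave 7 lists, of which 3 were among the 9, with 6 lost and 4 gained (luminal secretory, mesenchymal, ribosomal protein and oxidative phosphorylation genes). Of the 9 lists, 4 passed whichever library was left out. The changes between cancer and benign tissue in basal and in luminal cells had a Pearson r of 0.232 across genes (Spearman 0.242, jackknife error of r 0.159). Basal and luminal libraries of each tissue shared donors, so these changes were not independent, and r need not reflect tissue.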

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

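The tests of donor differences, benign cells, luminal RNA and endothelial cells were chosen after the results were seen, and the splits of the libraries were read after the counts were known. Of 200 groups of 5 libraries examined for a library far from the other 4, 12 had one, where chance gives about 10.

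Estimated depth was 62.0 M reads in cancer luminal replicate 1, against 13.0 to 21.2 in the rest of its group. The mean log2 level of ribosomal protein genes was also apart in cancer luminal replicate 1, at 11.22 against 11.69 to 11.85. ITGA6 stood at 12.56 in cancer luminal replicate 5 (13.40 to 13.72 in the others), and club and hillock cell markers there at 8.99 (11.14 to 11.81). TP63 was 13.79 in benign basal replicate 5 (12.96 to 13.20), and myeloid cell markers there averaged 3.27 (2.34 to 2.54). KRT8 was 12.84 in cancer luminal replicate 2 (11.98 to 12.14), and AMACR 10.49 in benign luminal replicate 2 (8.05 to 8.47). Proliferation genes averaged 4.59 in cancer basal replicate 4 (4.94 to 5.07), and endoplasmic reticulum genes 12.40 in cancer basal replicate 5 (11.72 to 11.88). NF-kB and cytokine genes averaged 10.58 in benign luminal replicate 3 (11.63 to 12.03), and genes known to be low in prostate cancer 6.83 in cancer basal replicate 1 (7.53 to 7.81).

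The basal to luminal change of 9 lists differed between the tissues by camera at its preset correlation, and in none of them with an estimated correlation (adjusted p of at least 0.141). The mean difference, cancer minus benign, was 0.61 for basal epithelial markers, -0.47 for proliferation genes, 0.41 for immediate early genes, 0.40 for histone genes and -0.64 for genes known to be high in prostate cancer. It was 0.47 for genes known to be low in prostate cancer, -0.74 for fibroblast markers, -0.13 for endoplasmic reticulum genes and 0.14 for ribosome biogenesis genes. Fibroblast means ranged from 3.5 to 9.11 among the cancer luminal libraries.

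Other splits of the libraries separated the gene counts from the list counts. Of 100 splits for basal against luminal cells, only the real split reached 4699 genes in benign tissue (highest other 1184). The same held for 5251 genes in cancer tissue (765) and 7747 for the mean (2). Splits that part as many donor pairs, of which there were 10, 20 and 3, gave at most 0, 68 and 0 genes. Only these keep the pairing by donor. In benign tissue and for the mean they are too few to exclude chance by themselves. For list counts at the preset correlation chance was not excluded: 5, 6 and 6 of 100 splits gave as many as the real 17, 18 and 18 lists, with 20 the highest other in each. Among the splits that part as many donor pairs, 1 of 10, 0 of 20 and 1 of 3 gave as many lists, with highest values of 18, 17 and 18. For the gene counts of 0 between tissues and for the interaction the splits decide nothing, since each of 100 splits gives at least 0. Some splits called many genes, up to 394 in basal cells, 303 in luminal cells and 1486 for the interaction, while the median split called 0. What those splits part was not tested. The 8, 16 and 9 lists that passed there were reached by 46, 7 and 51 of 100 splits, with 19, 20 and 18 the highest others. The median other split passed 7, 10 and 9 lists there, and 11 in each of the basal against luminal contrasts. A list call at the preset correlation is therefore weak evidence by itself, however small its adjusted p.

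The absence of called genes between cancer and benign tissue was weighed first. Differences between donors may hide a tissue difference, and the values do not decide this. In basal cells, where 4 donors gave both tissues, the random donor block called 1 gene, but it raised the unadjusted p-values under 0.05 from 720 to 1663, with 891 expected by chance. In luminal cells, where 2 donors gave both, the block called 0 genes, and too few pairs keep this open. Cells of benign glands in the libraries from cancer tissue may also hide a difference: the mean of genes known to be high in prostate cancer was 0.64 log2 units higher in cancer luminal libraries, with an exact permutation p (both tails) of 0.254, which leaves this open. Benign cells in the basal libraries from cancer tissue were not tested for. The tumor content of that tissue was not given in the sources used here. A small biological difference in these sorted cells was not tested apart from these.

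Luminal transcripts in basal libraries were weighed next, because benign basal replicate 5 and cancer basal replicate 5 lay nearest to the luminal libraries on component 1. In a fit without both, 72 genes had a mean log2 level of at least 9 in luminal libraries and were at least 3 log2 units lower in basal ones. Of these, 80.6% and 87.5% exceeded the mean of the other basal libraries. The median excess over all 72 genes was 7.0% and 6.6% of the luminal level. The genes were picked as low in the other basal libraries, and the 2 libraries for lying near the luminal ones. Some excess was therefore built in. In the other basal libraries the share ran from 8.3% to 84.7% and the median excess from -3.9% to 3.5%. The median excess was thus higher in the 2 libraries, while the share overlapped nearly in full. Because of how genes and libraries were picked, RNA of luminal cells in these 2 libraries cannot be told apart from expression by basal cells. Without both libraries, a setting chosen after seeing the data, limma called 4169 genes in benign and 5090 in cancer tissue.

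NOTCH4 and endothelial markers, both higher in basal libraries, were weighed together because endothelial cells also carry CD49f, although the epithelial gate should remove them. Endothelial cells as the source of NOTCH4 are argued against: NOTCH4 lay 4.79 ± 1.24 log2 units (SD, n = 10 basal libraries) above the mean of the 12 endothelial markers, and stood at 10.04 in the library where that mean was lowest, 2.64. For the endothelial markers themselves such cells remain a candidate source. The markers varied together across basal libraries (mean pairwise correlation 0.75), more than 100% of 1000 random lists of like size and level, whose median was 0.08. Levels of the abundant endothelial genes PECAM1 (5.21) and VWF (4.86) in benign basal cells were low beside COL17A1 (13.19), and ERG and KDR of that list were also detected in luminal libraries. ERG exceeded a log2 level of 10 in 3 of 5 cancer and 1 of 5 benign luminal libraries. The list averaged 3.75 and 3.87 in these groups, so ERG did not follow it there. Expression of the endothelial markers by basal cells was not tested.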

How the results depend on the processing

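The basal against luminal gene counts stayed within 1.5 times under most settings, and 0 named genes past the threshold changed sign. Exceptions in the counts were benign tissue with the donor as a replicate block, 7087 as a random and 7364 as a fixed effect, and the mean of both tissues with genes at or above the median level, 4901, where 8912 genes were tested. Between tissues, the replicate block called 1 gene in basal cells as a random and 1 as a fixed effect (ERP27). In luminal cells the offset of 16 called 1 gene, HAMP, and leaving out single libraries gave 0 to 1: CARTPT without benign luminal replicate 4 and CSRNP1 without cancer luminal replicate 1. These 3 genes were named after their values were seen. With the block as a random effect, fibroblast markers passed for the mean (adjusted p = 0.0386), and for the interaction luminal secretory (0.038), ribosomal protein (0.000443) and oxidative phosphorylation genes (0.0113) passed and endoplasmic reticulum genes did not (0.494). The list counts fell to 1 in each basal against luminal contrast and to 0 in the other contrasts with an estimated correlation between genes, which widens the test for lists that vary together. Fry gave 15, 14 and 17 lists for basal against luminal cells in benign tissue, in cancer tissue and for the mean. Of these, 13, 13 and 15 were among the 17, 18 and 18 that camera passed at the preset correlation. It gave 0 lists for both tissue contrasts and the interaction. For cancer against benign basal cells 4 lists passed after quantile normalization, and leaving out single libraries gave 5 (without benign basal replicate 3) to 13 (without cancer basal replicate 1). For luminal cells 10 passed with genes at or above the median level, and single libraries gave 9 to 17 (9 without cancer luminal replicate 5 and 10 without cancer luminal replicate 3). The correlation of the population changes was 0.937 at or above the median level, 0.917 with the offset of 16 and 0.829 with the fixed donor block, against a jackknife error of 0.035. Component 1 held 42.3% of the variance of the 5000 most variable genes and 38.0% of that of all tested genes. Unless a smaller set of genes or the estimated correlation accounts for it, the cause was not tested. Fits to the groups compared alone do not apply to the mean and the interaction. Depth limits the genes near 0, which the deposited scale compresses.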

Other observations

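The Notch list did not pass, and its members went both ways (benign tissue, 5 rose and 4 fell of 17). The genes in this part were named after their values were seen. In benign tissue the receptors NOTCH4 (4.07) and NOTCH1 (1.45, adjusted p = 0.0177) and the ligands JAG2 (2.34, adjusted p = 0.00162) and JAG1 (1.08, adjusted p = 0.00321) were higher in basal cells. The ligand DLL4 was 4.28 log2 units lower in basal cells, at -4.28 ± 0.49 (adjusted p = 3.82e-06), and NOTCH2 (-0.50, adjusted p = 0.0033) and the target HEY2 (-1.34, adjusted p = 0.022) were lower too. In cancer tissue DLL4 stood at -4.55 (adjusted p = 1.39e-06), NOTCH4 at 4.90 and JAG2 at 2.99 (adjusted p = 0.000143).

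The stem and progenitor list did not pass in benign tissue (adjusted p = 0.771) or cancer tissue (adjusted p = 1). Of its 18 genes 2 rose and 2 fell in benign tissue, and 1 rose and 1 fell in cancer tissue (2 and 2, then 0 and 1, adjusted over the list alone). SOX2 was higher in basal cells in benign (0.82, adjusted p = 0.0239) and cancer tissue (0.78, adjusted p = 0.0272), and PROM1, which encodes CD133, was lower in cancer tissue (-3.43, adjusted p = 0.00644). CD44 and BMI1 did not pass in either tissue: CD44 differed by -0.07 and 0.29 and BMI1 by 0.19 and 0.30. MYC was higher in basal cells (0.86, adjusted p = 0.000664, and 1.17, adjusted p = 2.52e-05), as were FOSL1 (0.91, adjusted p = 0.00808, and 1.51, adjusted p = 8.7e-05) and the cytokine gene IL1B (3.08, adjusted p = 0.000988, and 3.38, adjusted p = 0.000368). ATF3 (-1.49, adjusted p = 0.00078, and -1.33, adjusted p = 0.00174) was lower. These genes do not speak for the immediate early or the NF-kB and cytokine lists, which passed in neither tissue. In benign tissue the mean log2 level of immediate early genes was 11.47 in basal and 11.91 in luminal libraries. For NF-kB and cytokine genes it was 11.17 and 11.59. VIM, a mesenchymal filament gene, was lower in basal cells of benign tissue (-1.39, adjusted p = 0.0197) while AXL was higher (1.41, adjusted p = 0.012).

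ERG varied within groups: its log2 level was above 10 in 3 of 5 cancer luminal and 1 of 5 benign luminal libraries.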
